A study of Mus musculus with 8 samples.

How the data were processed

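RNA was sequenced from primary aortic endothelial cells of mice in which Ptbp1 was deleted in endothelium (a tamoxifen-inducible Cre driven by the Cdh5 promoter acting on a floxed Ptbp1) and of control mice, called wild type below. Per the labels, cells freed from the aortic lumen with collagenase were grown on collagen in 5% oxygen and 5% carbon dioxide for 4 days. They were then kept for 24 h with or without 30 ng/mL TNF in medium holding 10% mouse serum, and cells were then sorted as CD45-negative cells carrying Icam2 and Cd31. The 8 libraries form 4 groups of 2: wild type untreated, wild type with TNF, knockout untreated and knockout with TNF. Replicate 1 of each group came from a female and replicate 2 from a male, so the libraries of a group came from separate mice; how many mice went into a culture is not given in the sources used here. An untreated and a TNF library of the same genotype and sex share a number in the labels, whose meaning is not stated. These were summed as 1 culture in a separate fit. Where libraries that share such a number came from the same mouse, p-values measure only the spread between these libraries, which may in part be technical.

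The expected counts (RSEM's estimated counts) per gene were made by the authors with RSEM after STAR alignment to mm9, per the submitters' processing notes; versions are not given in the sources used here. They list 21674 genes under RefSeq symbols, some of them older names: Rod1 is Ptbp3, Pkm2 is Pkm, Mycl1 is Mycl, Ccrl1 is Ackr4, Fam105b is Otulin and Ero1l is Ero1a. The 1 row without a gene name, 0.028 to 0.037% of the counts, was left out. A second deposited set, per the file headers, gives gene TPM with read estimates for 55335 genes, junction counts, and the inclusion fraction (percent spliced in, PSI) with the total reads of each exon or splice event, called a node. The tool behind that set is not given in the sources used here. Its junction counts were deposited with coordinates, and 99.92% of junction ends lie at exon ends of GENCODE M21, so exon positions are given in mm10 coordinates with that annotation. Total reads behind PSI are rounded to 3 digits in the deposited files where they are large. Isoform tables were not used here. Library totals were 143.1 to 169.1 M (mega) expected counts and 120.8 to 138.0 M junction reads. Counting error was small beside the spread between libraries: chi-square per degree of freedom between replicates ran from 76.9 to 315.8, and no pair of libraries agreed within sampling noise. Whether the counting used strand is not given in the sources used here, so overlapping genes are uncertain, as are close paralogs.

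Expected counts were rounded to whole numbers. The test was edgeR 4.0.16's quasi-likelihood F test (robust) in R 4.3.3, with TMM normalization, the filterByExpr filter (14079 genes) and all 8 libraries in a single fit. The model had a term for each group and for sex, so that the groups share the estimate of the spread (residual degrees of freedom 3, common biological coefficient of variation 30.4%). Contrasts were TNF in each genotype, TNF averaged over genotypes, knockout against wild type without and with TNF, and the interaction. Knockout was also set against wild type on counts summed per culture (14083 genes). Adjusted p means Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes carry an approximate standard error (SE). It was worked back as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalised and come with the SD over 2 libraries. On simulated data for TNF in knockout cells (13798 genes), the test recovered 71% of genes changed 2-fold and 95% of genes changed 8-fold, with 9 false calls among 175. The simulation gave each gene the same spread in every group and no effect of sex or culture. The real libraries may be less regular, so these shares do not show how many such changes the test misses in them. Gene lists, 27 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists; the estimated correlation and fry were alternatives. A list called at the preset correlation held with an estimated correlation in 1 case, the NF-kB list in the averaged TNF comparison.

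The genes named in the text follow a rule. It takes genes with an adjusted p under 0.05, a mean of at least 5 CPM in a group and the same direction in the female and the male pair. Of these it names the 8 largest rises and the 8 largest falls, without predicted genes, pseudogenes and sex-linked genes, and, with no minimum level, up to 4 members per list with the smallest p. Where fewer than 5 genes pass, it names the 5 smallest p, said not to pass. It adds 15 genes always given (among them Ptbp1, Ptbp2, Vcam1, Icam1, Sele, Ccl2, Nfkbia, Klf2, Klf4, Nos3 and Pkm). Some genes that the rule takes are not reported here. Every gene given as having risen or fallen moved the same way in both sexes unless stated. The contrasts, lists, naming rule and most alternatives were fixed before the data were examined.

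For splicing, inclusion and exclusion reads of cassette exons were rebuilt from PSI and total reads and tested with edgeR's quasi-likelihood test for a shift of the ratio. Of 173278 cassette nodes, 93169 had at least 10 reads in every library and 32840 of these could be tested; a call also needed a PSI change of at least 0.1. On simulated data for knockout against wild type untreated this test recovered 0% of PSI shifts of 0.3, so its calls carry no information on absence. A test limited to the 5220 nodes with a mean PSI between 0.05 and 0.95, chosen after seeing the data, recovered 40.5% of such shifts with 0 false calls among 81. The simulation gave all exons the same median spread between libraries. Replicates of real exons differed by 24.2 to 28.3 percentage points at the 95th percentile, depending on the group. The simulated false calls thus do not measure how many of the real calls are false. The exons named are those of 2 fixed lists that were called and the 6 largest rises and falls.

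Alternatives were DESeq2 1.42.0 and its size factors, no filter or at least 5 CPM in 2 libraries, no sex term, limma-voom with the culture as a random effect, the culture number as a block, and a 2-fold minimum. They also included limma-trend on log2(TPM + 1) of the second set (12701 genes matched by symbol), leaving out each library, read minimums and PSI minimums for exons, and prior counts for the response size. Added after seeing the data were fits on the 4 libraries compared, a fit without a genotype-by-TNF term, and removal of each library's trend with gene length.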

Results

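The series asked how endothelial cells that lack the splicing factor Ptbp1 differ from control cells at rest and after an inflammatory signal. Aortic endothelial cells from mice with an endothelial knockout of Ptbp1 and from wild-type controls were cultured, left untreated or given TNF, sorted and sequenced. Each of the 4 groups held 1 female and 1 male library. Expected counts summed to 157.0 and 159.3 M in the untreated knockout libraries (female, then male), 154.4 and 148.0 M in the knockout libraries with TNF, 143.1 and 169.1 M in untreated wild type, and 152.2 and 151.5 M in wild type with TNF. Replicates correlated across genes at 0.9947 (wild type untreated), 0.9946 (knockout untreated), 0.9893 (knockout with TNF) and 0.988 (wild type with TNF) on log2 CPM.

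Ptbp1 transcript was nearly lost from every knockout library. It stood at 676.5 and 628.6 CPM in untreated wild type and 645.8 and 651.9 CPM in wild type with TNF. In the knockout it was 3.54 and 2.96 CPM untreated (564 and 478 counts) and 9.30 and 5.87 CPM with TNF (female, then male). Without TNF the log2 fold change was −7.66 ± 0.21 (SE; edgeR, Benjamini-Hochberg adjusted p = 2.21e-05). Its paralog Ptbp2, the form used by neurons, rose from 6.05 ± 0.65 to 131.7 ± 8.1 CPM (SD, n = 2 libraries per group), a log2 fold change of 4.44 ± 0.23 that passed edgeR's test with a Benjamini-Hochberg adjusted p of 0.000283. The third member, Ptbp3 (listed as Rod1), was at 66.0 to 111.7 CPM in all 8 libraries and did not pass between genotypes (log2 fold change 0.17 untreated and 0.34 with TNF). The 3 paralogs are similar in sequence, so small counts of any of them are uncertain, the residual Ptbp1 counts included.

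**Figure D1:**
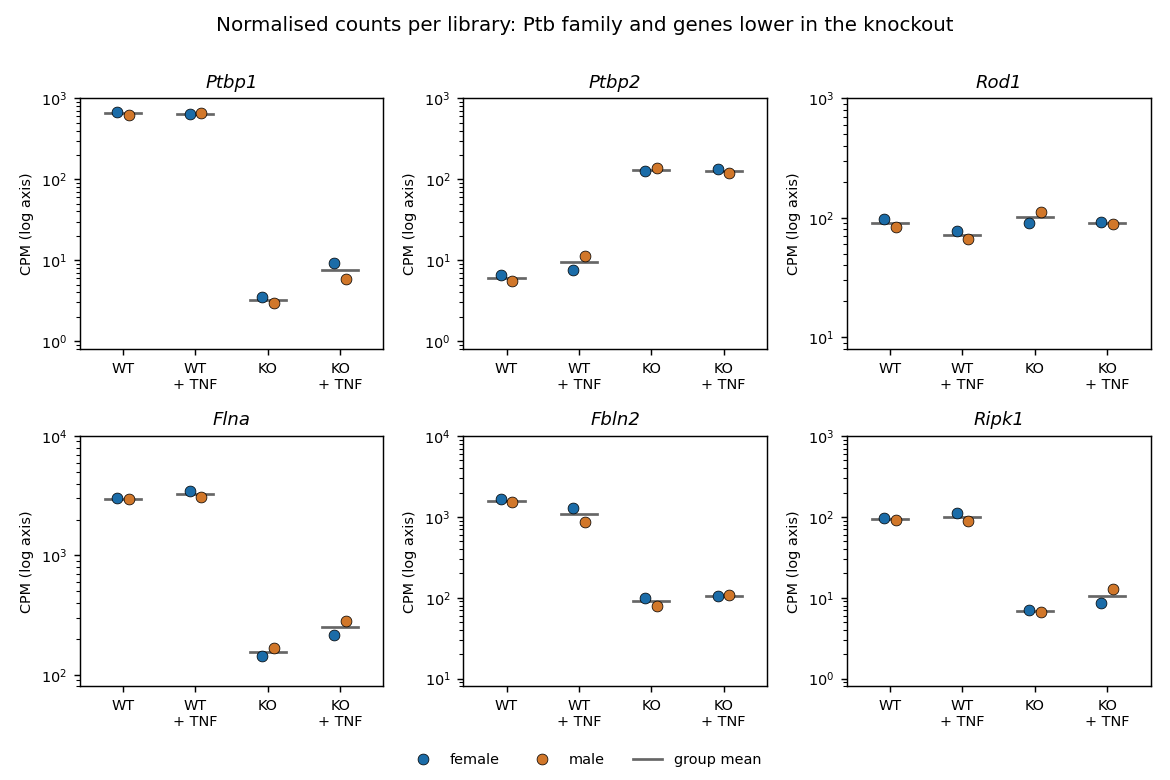
Level of 6 genes (Ptbp1, Ptbp2, Rod1, Flna, Fbln2 and Ripk1) in each of the 8 libraries, in TMM-normalised CPM on a log axis, by group; each point is a library, coloured by sex, and the bar is the group mean. Ptbp1 lies at 628.6 to 676.5 CPM in the wild-type libraries and at 2.96 to 9.30 CPM in the knockout libraries, and Ptbp2 at 5.59 to 11.4 CPM against 118 to 137.4 CPM.

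In wild-type cells with TNF, 17 of 42 NF-kB and TNF target genes rose, and 8 of 29 matrix genes, 4 of 18 flow-induced genes and 4 of 20 arterial and Notch genes fell. Ccl2, which attracts monocytes, rose from 99.9 to 1465 CPM (log2 fold change 3.86 ± 0.33 SE), and Vcam1, an adhesion receptor for leukocytes, from 1140 ± 98 to 2487 ± 85 CPM (1.13 ± 0.11). Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, rose from 73.6 to 202.1 CPM (1.47 ± 0.14). Elastin (Eln) fell from 365.9 to 6.92 CPM (−6.05 ± 0.52) and Fbln5, which helps assemble elastic fibres, from 1545 ± 21 to 165.4 ± 34 CPM (−3.24 ± 0.13). The edgeR Benjamini-Hochberg adjusted p-values of these genes ran from 0.000413 for Fbln5 to 0.00621 for Vcam1 and Nfkbia. The other large rises were Slc11a1, a metal transporter of phagocytes (3.69), Ubd, a ubiquitin-like protein (3.27), Psg22 (3.17), the chemokine Ccl7 (3.08), Foxh1 (2.83), Mycl1 (2.77) and Nod2, a sensor of bacterial wall fragments (2.11). The other large falls were Ccrl1, a scavenging chemokine receptor (−3.85), Cdh3 (−3.83), the endothelial lectin Clec14a (−3.41), the Wnt modulator Sfrp2 (−2.65), Tmtc1 (−2.59) and Pi16 (−2.46).

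Of 42 measured NF-kB and TNF target genes, 17 rose with TNF in wild type, 0 fell and 25 did not pass; adjusted over the list alone, 28 rose and 1 fell. Camera gave the list a Benjamini-Hochberg adjusted p of 3e-17, and adjusted p = 0.0513 with an estimated correlation. Among its members Tnfaip3, an editor of ubiquitin that shuts NF-kB signalling off, rose by 1.61 ± 0.16. Several classic adhesion and cytokine genes did not pass: log2 fold changes were 0.39 for Icam1, 0.42 for Sele, −0.11 for Selp and 1.07 for Cxcl1, and Il6 was below 1 CPM in every group. Of 18 genes that laminar flow induces, 4 fell (Timp3 −1.93, Ptgs1 −1.33, Cyp1b1 −1.06 and Smad6 −1.05) and 0 rose; adjusted over the list alone, 9 fell (camera Benjamini-Hochberg adjusted p = 8.69e-06; adjusted p = 0.188 with an estimated correlation). Klf2 (−0.07) and Nos3 (0.00), the best-known genes of that response, did not pass, nor did Klf4 (−0.72). Of 20 arterial and Notch genes 4 fell, among them the gap-junction genes Gja4 (−1.72) and Gja5 (−1.26) and the kinase Bmx (−2.03), and 0 rose; adjusted over the list alone, 9 fell and 2 rose (camera Benjamini-Hochberg adjusted p = 5.49e-05; adjusted p = 0.663 with an estimated correlation). Of 29 endothelial identity genes 4 fell (Ptprb −1.18, Vwf −0.93 and Flt1 −0.85, with Clec14a) and 0 rose; adjusted over the list alone, 11 fell and 1 rose (0.0114; adjusted p = 0.689 with an estimated correlation; both camera, Benjamini-Hochberg).

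Of 29 matrix and basement membrane genes, 8 fell with TNF in wild type, among them the collagen Col8a1 (−1.45), the proteoglycan Bgn (−1.43), Eln and Timp3, and 0 rose; adjusted over the list alone, 12 fell and 1 rose (camera Benjamini-Hochberg adjusted p = 8.14e-07; adjusted p = 0.663 with an estimated correlation). Beside them, markers of fibroblasts moved: 4 of 15 fell (Col3a1 −1.69, Col1a1 −1.51, Lox −1.43 and Pi16) and 0 rose; adjusted over the list alone, 8 fell and 2 rose (0.00269; adjusted p = 0.384 with an estimated correlation; both camera, Benjamini-Hochberg). Of 14 smooth muscle markers, Pdgfrb fell (−2.12) and Smtn rose (0.59), while Acta2, the most abundant, was 2317 and 2590 CPM (0.15, not past the test).

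In all, edgeR called 145 genes higher and 289 lower with TNF in wild type, 434 of 14079 (Benjamini-Hochberg), and 2955 genes had an unadjusted p under 0.05. The number of calls rested on single libraries: it was 31 without untreated wild type replicate 1, 2 without untreated wild type replicate 2 and 2274 without wild type with TNF replicate 1. On the TPM scale the split was 84 higher and 295 lower, and with the length trend of each library removed 431 higher and 550 lower. DESeq2 called 1732 genes, limma-voom 720 and edgeR on the 4 libraries alone 665.

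**Figure D2:**
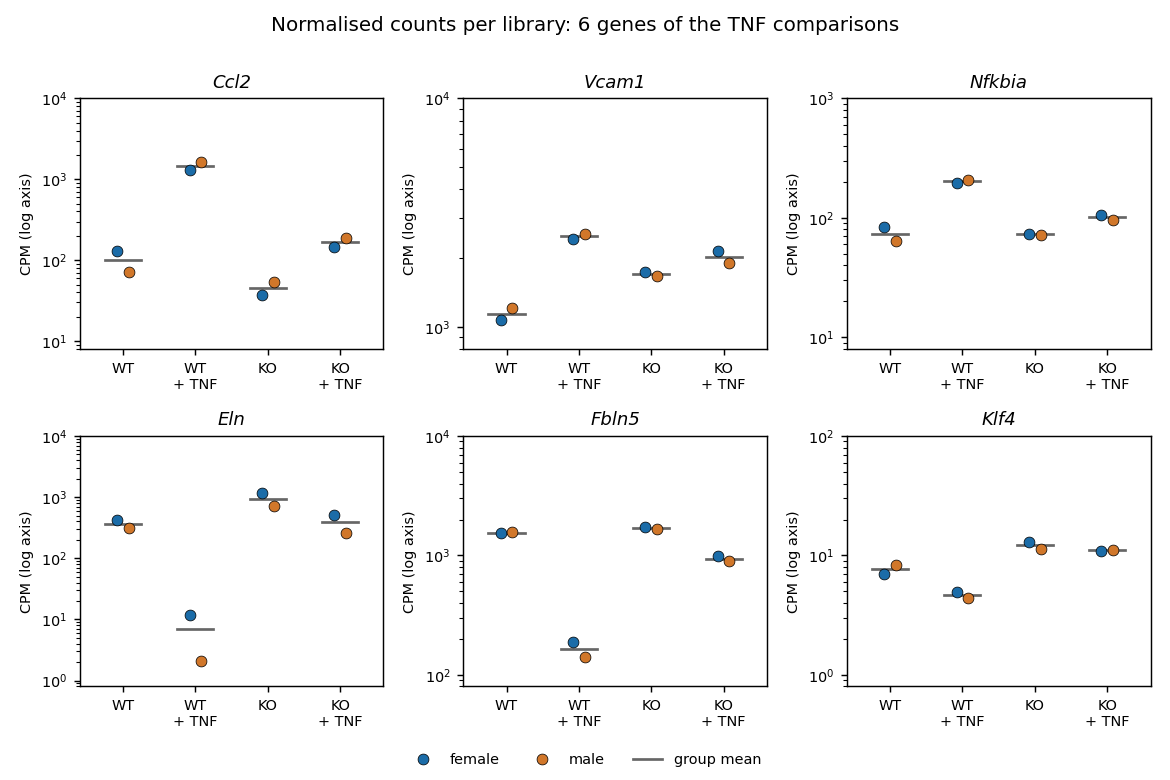
Level of 6 genes (Ccl2, Vcam1, Nfkbia, Eln, Fbln5 and Klf4) in each of the 8 libraries, in TMM-normalised CPM on a log axis, by group; each point is a library, coloured by sex, and the bar is the group mean. Mean Ccl2 goes from 99.9 to 1465 CPM with TNF in wild type and from 45.7 to 166.1 CPM in the knockout, and mean Fbln5 from 1545 to 165.4 CPM and from 1703 to 941.5 CPM.

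In knockout cells, TNF gave Ccl2, Vcam1, Nfkbia, Eln and Fbln5 fold changes of the same sign as in wild type, and 0 genes passed edgeR's test with Benjamini-Hochberg adjustment (smallest adjusted p 0.299). There, 488 genes had an unadjusted p under 0.05, where 704 would be expected by chance. DESeq2 called 46 genes, limma-voom and limma-trend on TPM 0, and edgeR on the 4 knockout libraries alone 20. The 5 genes with the smallest p, none of which passed, had log2 fold changes of 1.58 (Mycl1), 2.47 (Foxh1), 1.21 (Ptbp1), −0.86 (Fbln5) and 1.87 (Ccl2). Vcam1 went from 1709 ± 51 to 2027 ± 175 CPM (log2 fold change 0.25) and Nfkbia from 72.6 to 101 CPM (0.47). In the NF-kB list 36 of 42 genes had a positive fold change and 10 passed as higher when adjusted over the list alone, against 0 over all genes (camera Benjamini-Hochberg adjusted p = 2.36e-15; adjusted p = 0.0594 with an estimated correlation). Camera called 7 other lists, with 0 members past the test over all genes. They were oxidative phosphorylation (8.52e-07; 74 of 76 fold changes negative), ribosomal proteins (0.00332; 74 of 78 negative, but 40 positive with the length trend of each library removed), arterial and Notch genes (0.000381; 3 fell adjusted over the list alone), cholesterol synthesis (4.28e-06; 19 of 21 fold changes negative), smooth muscle markers (0.0137), tip cell genes (0.0217) and antigen presentation (0.0354). Their adjusted p = 0.798, 0.936, 0.675, 0.278, 0.675, 0.781 and 0.675 with an estimated correlation, in that order. Without knockout with TNF replicate 2, 76 ribosomal protein and 58 oxidative phosphorylation genes had positive fold changes.

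The difference between the genotypes was tested directly as the interaction. Only Fbln5 passed: its fall with TNF was smaller in the knockout by 2.38 ± 0.18 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0269). Its call was lost without any 1 of the 4 untreated libraries or of the 2 knockout libraries with TNF, where edgeR's Benjamini-Hochberg adjusted p ran from 0.0742 (without knockout with TNF replicate 2) to 0.525 (without untreated wild type replicate 2). In between stood 0.161 without untreated wild type replicate 1, 0.173 without knockout with TNF replicate 1, 0.285 without untreated knockout replicate 2 and 0.384 without untreated knockout replicate 1. Vcam1 (−0.88 ± 0.15), Nfkbia (−0.99 ± 0.19), Ccl2 (−1.99 ± 0.43) and Eln (4.73 ± 0.62) did not pass. An unadjusted p under 0.05 was found for 1130 genes. DESeq2 called 135 positive and 36 negative, limma-voom 2 and limma-trend on TPM 0, and without wild type with TNF replicate 1 edgeR called 591. In the NF-kB list 34 of 42 interactions were negative (median −0.58), with a camera Benjamini-Hochberg adjusted p of 1.96e-09 and adjusted p = 0.133 with an estimated correlation. Measured per culture, the median log2 change of the NF-kB list with TNF was 0.98 and 1.36 in wild type and 0.51 and 0.45 in the knockout (female, then male). With 2 cultures per genotype the exact two-sided permutation test gave p = 0.333, the smallest it allows. On log2(TPM + 1) the medians were 0.678 and 0.802 against 0.403 and 0.437.

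Averaged over genotypes, TNF raised 95 genes and lowered 177 (edgeR, Benjamini-Hochberg; 2440 at an unadjusted p under 0.05). Large rises were those of Ccl2 (2.86 ± 0.23), Slc11a1 (2.67), Foxh1 (2.65), Psg22 (2.53), Ubd (2.39), Ccl7 (2.20), Mycl1 (2.17) and Irf5, a regulator of inflammatory cytokines (1.59). Large falls were those of Eln (−3.69), the oxidase Aox1 (−2.90), Cdh3 (−2.67), Cdo1 (−2.23), Clec14a (−2.05), Fbln5 (−2.05 ± 0.09), Sfrp2 (−1.74) and Cxcr7 (−1.64). In the NF-kB list 15 of 42 rose and 0 fell, and adjusted over the list alone 26 rose and 1 fell (camera Benjamini-Hochberg adjusted p = 3.86e-20; adjusted p = 0.0397 with an estimated correlation). Vcam1 rose by 0.69 and Nfkbia by 0.97. Of the 95 genes called higher, 92 had a larger fold change in wild type (median 1.07 against 0.55), and 177 of the 177 called lower (−1.24 against −0.36). These genes were chosen by a test that both genotypes enter, which favours genes with a large change in either, so these shares are not a test of the difference. The count of calls was 15, 5, 21 and 3 without untreated knockout replicate 1 or 2 or untreated wild type replicate 1 or 2, and 75 without knockout with TNF replicate 2. It was 1306 and 716 without wild type with TNF replicate 1 or 2. DESeq2 called 1269 genes, limma-voom 493, edgeR with length trends removed 713 and edgeR without a genotype-by-TNF term 1.

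Without TNF, knockout cells had lost most transcript of Flna, Fbln2 and Ripk1. The actin cross-linker Flna fell from 2997 ± 36 to 156.6 ± 16 CPM (log2 fold change −4.26 ± 0.16 SE). Fbln2, a matrix glycoprotein, fell from 1580 to 90.0 CPM (−4.14 ± 0.17), and Ripk1, the kinase that carries the signal of the TNF receptor to survival or death, from 93.6 ± 3.8 to 6.86 ± 0.27 CPM (−3.77 ± 0.23). The edgeR Benjamini-Hochberg adjusted p-values of these 3 ran from 7.79e-05 (Flna) to 0.000478 (Ripk1). Other large falls were those of the interleukin-3 receptor subunit Il3ra (−3.66), Pgm1 (−3.57, but 0.148 on the TPM scale of the second table) and Abhd14b (−3.49). Large rises among genes of at least 5 CPM, besides Ptbp2, were Fsd1l (3.36), the chloride transporter Clcn6 (3.12), the vesicle protein Vamp1 (2.30), Zmat1 (2.28), Gpr21 (2.22), the retinal dehydrogenase Aldh1a1 (2.15) and Mogat2 (2.05). Pkm2, pyruvate kinase, fell from 3782 ± 78 to 1622 ± 30 CPM (−1.22 ± 0.09).

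In the NF-kB list, compared between untreated genotypes, 2 of 42 rose and 1 fell (adjusted over the list alone, 5 and 3; camera Benjamini-Hochberg adjusted p = 0.276). Sele, an adhesion molecule for rolling leukocytes, rose from 36.3 to 59.0 CPM (0.70) and Vcam1 by 0.59, while Ripk2 fell (−1.28). Ccl2 (−1.15), Icam1 (0.45) and Nfkbia (−0.01) did not pass. Of 25 parts of the TNF receptor and NF-kB pathway, 3 fell (Ripk1, the adaptor Tradd −0.94, and Fam105b, a linear-ubiquitin hydrolase, −0.71) and 0 rose; adjusted over the list alone, 4 fell and 3 rose (camera Benjamini-Hochberg adjusted p = 0.752). Of 20 antigen presentation genes H2-Q6 rose (1.77), and 4 rose adjusted over the list alone (0.00972; adjusted p = 0.543 with an estimated correlation; both camera, Benjamini-Hochberg). Smooth muscle and fibroblast markers were higher in places: 3 of 14 rose in the first (Cspg4 3.72, at 0.27 and 4.31 ± 3.47 CPM, Tagln 1.20 and Acta2 0.76, from 2317 to 3919 CPM). In the second 3 of 15 rose (Dcn 1.97, Mfap5 1.72 and Lox 1.10), 4 of each adjusted over the list alone, and 0 fell. Their camera Benjamini-Hochberg adjusted p-values were 0.0193 and 0.0206, and adjusted p = 0.523 for both with an estimated correlation. Of 19 glycolysis genes Pkm2 and Pfkl (−0.67) fell (3 adjusted over the list alone), and of 19 p53 targets Gdf15 (0.78) and Cdkn1a (0.66) rose (4 adjusted over the list alone). Camera gave Benjamini-Hochberg adjusted p-values of 0.00201 and 0.00722, and adjusted p = 0.523 for both with an estimated correlation. Of 6 mesothelial and adipocyte markers Krt18 fell (−1.61), 2 fell adjusted over the list alone and 6 had negative fold changes (camera Benjamini-Hochberg adjusted p = 0.025; adjusted p = 0.523 with an estimated correlation). Markers of leukocytes (8 measured) had 0 members past the test.

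edgeR called 127 genes higher and 157 lower in the untreated knockout (Benjamini-Hochberg; 2725 genes at an unadjusted p under 0.05). The count fell without any 1 of the 4 libraries: 38 and 35 genes were called without untreated knockout replicate 1 or 2, and 32 and 36 without untreated wild type replicate 1 or 2. DESeq2 called 776 higher and 621 lower, edgeR on the 4 libraries alone 1115 and 1058, and edgeR with length trends removed 436 and 464.

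With TNF, 14 of 29 matrix genes and 8 of 18 flow-induced genes were higher in the knockout than in wild type (4 and 0 lower). Lower were 74 of 78 ribosomal protein genes, 12 of 42 NF-kB and TNF target genes and 8 of 19 glycolysis genes (0, 2 and 2 higher). Eln was 6.92 ± 6.9 CPM in wild type with TNF and 386.9 ± 181 CPM in the knockout (log2 fold change 6.02 ± 0.51 SE). Fbln5 was 165.4 against 941.5 CPM (2.52 ± 0.13), while Ccl2 was 1465 ± 236 against 166.1 ± 30 CPM (−3.14 ± 0.32). The edgeR Benjamini-Hochberg adjusted p-values were 0.00117, 0.000255 and 0.00273. Other large rises were Anxa8 (4.63), the oestrogen receptor Esr1 (3.97), Ptbp2 (3.74), Fsd1l (3.65), Vamp1 (3.36), Tmtc1 (3.28) and the neuronal GABA-B receptor Gabbr1 (3.15). Large falls there were Ptbp1 (−6.45), Flna (−3.72), Il3ra (−3.65), the actin regulator Raph1 (−3.45), Fbln2 (−3.31), Ripk1 (−3.24) and Ccl7 (−3.15).

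Of the 42 NF-kB and TNF target genes 12 were lower in the knockout with TNF, among them Ripk2 (−1.73), Relb (−1.06) and Nfkbia (−1.01), and 2 were higher; adjusted over the list alone, 15 and 7 (camera Benjamini-Hochberg adjusted p = 0.00663; adjusted p = 0.326 with an estimated correlation). Vcam1 (−0.30) did not pass. Of the 18 flow-induced genes 8 were higher and 0 lower, with Ptgs1, a prostaglandin synthase (2.46), Timp3, a protease inhibitor (2.01), the transcription factor Klf4 (1.24, 4.65 against 11 CPM) and Smad7 (0.99); adjusted over the list alone 9 were higher (0.000716; adjusted p = 0.326 with an estimated correlation; both camera, Benjamini-Hochberg). Of 29 matrix genes 14 were higher, among them Col8a1 (1.39) and the protease Mmp2 (1.11), and 4 lower; adjusted over the list alone, 16 and 4 (camera Benjamini-Hochberg adjusted p = 0.000255; adjusted p = 0.765 with an estimated correlation). Fibroblast markers went with them: 8 of 15 were higher over all genes and over the list alone, and 0 lower, with Lox at 2.18, Col1a2 at 1.69 and Col3a1 at 1.54 (0.00134; adjusted p = 0.326 with an estimated correlation; both camera, Benjamini-Hochberg). Of 14 smooth muscle markers 4 were higher, with Pdgfrb at 1.87 and Tagln at 1.13, and Smtn was lower (−0.48); adjusted over the list alone, 7 and 2 (camera Benjamini-Hochberg adjusted p = 0.0846). Of 19 glycolysis genes 8 were lower, with Pkm2 (−1.41), Eno1 (−0.83), Pfkl (−0.74) and Pgk1 (−0.62), and 2 higher; adjusted over the list alone, 11 and 2 (camera Benjamini-Hochberg adjusted p = 0.00134; adjusted p = 0.736 with an estimated correlation).

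Genes of the ribosome and of respiration were lower as a block in the knockout with TNF: 74 of 78 ribosomal protein genes (median log2 fold change −0.96) and 55 of 76 oxidative phosphorylation genes (median −0.73), with 0 higher. The counts adjusted over the list alone were 77 and 68 (camera Benjamini-Hochberg adjusted p = 3.75e-26 and 1.96e-19; adjusted p = 0.748 and 0.765 with an estimated correlation). These genes are short, and the libraries differed in how level went with gene length. Spearman's rho between a library's deviation and length across genes was 0.135, 0.251, 0.228 and 0.356 in the knockout libraries (untreated, then with TNF, female before male) and −0.092, −0.148, −0.113 and −0.420 in the wild-type libraries. Across genes in the fifth of shortest length the median fold change was −0.37 and in the fifth of longest length 0.42. With each library's length trend removed, 36 ribosomal protein genes were lower (median −0.32), and 14 oxidative phosphorylation genes were lower and 3 higher. Without knockout with TNF replicate 2, 0 ribosomal protein genes passed (median −0.70).

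The same lists stood apart in the comparisons behind this difference, with 0 members past edgeR's test over all genes or adjusted over the list alone. Other fits called some. With TNF in wild type, DESeq2 called 31 ribosomal protein genes higher and 1 oxidative phosphorylation gene lower, limma-voom 2 and 1, and edgeR on the 4 libraries alone 18 and 0. In the untreated knockout DESeq2 called 0 and 2 lower, limma-voom 0 and 0, and edgeR on the 4 libraries alone 24 and 30. With TNF in wild type, 78 of 78 ribosomal protein genes (median 0.55) and 73 of 76 oxidative phosphorylation genes (median 0.25) had positive fold changes (camera Benjamini-Hochberg adjusted p = 7.32e-21 and 2.39e-06; adjusted p = 0.666 and 0.701 with an estimated correlation). Without wild type with TNF replicate 1, 72 and 36 of them passed as higher. Positive fold changes of oxidative phosphorylation genes numbered 28 without wild type with TNF replicate 2 and 32 with length trends removed (median −0.02, 3 past the test as lower), where 76 ribosomal protein genes were positive (median 0.24, 4 past it as higher). In the untreated knockout 77 of 78 ribosomal protein genes (median −0.32) and 72 of 76 oxidative phosphorylation genes (median −0.32) had negative fold changes (camera Benjamini-Hochberg adjusted p = 9.84e-08 and 3.21e-09; adjusted p = 0.675 for both with an estimated correlation). With length trends removed, 51 and 54 were negative, with medians of −0.09 and −0.10, and 0 and 2 passed.

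edgeR called 1559 genes higher and 1486 lower in the knockout with TNF (Benjamini-Hochberg, with 5232 at an unadjusted p under 0.05). With each library's length trend removed it called 1392 higher and 1634 lower. Of the 3045 genes first called, 2164 were called in the same direction by that fit. The genotypes differed in their length trend, so it may touch the whole comparison, not only the ribosomal and respiration lists. All groups shared the estimate of the spread, but replicates differed more with TNF than untreated. Their chi-square per degree of freedom was 315.8 (wild type) and 210.7 (knockout) with TNF, and 76.9 and 78.3 untreated. The shared estimate may thus call too many genes with TNF and too few untreated. On the 4 libraries of each comparison alone, the untreated comparison called more genes (2173) than that with TNF (219). On the TPM scale of the second table the split was 2494 higher and 627 lower, with a median over all genes of 0.217. That alternative also differs in the test, the quantification and the genes tested, and a change of size factors alone (RLE) gave 1565 higher and 1501 lower. The count was 4970 without wild type with TNF replicate 1, 1812 without wild type with TNF replicate 2 and 425 (306 higher, 119 lower) without knockout with TNF replicate 2, and 219 (141 higher, 78 lower) in a fit of the 4 libraries alone.

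The genotype comparisons without and with TNF share no library, and their calls overlapped. Of the genes called without TNF, 114 of the 127 genes higher and 138 of the 157 lower were called the same way with TNF, where independent lists of these sizes would share 14.1 and 16.6, and 0 were called the opposite way. The shares of independent lists take no account of the numbers that untreated and TNF libraries share, nor of the single fit behind both comparisons. Nor do they allow for the trends with gene length, which had opposite signs in the genotypes in both comparisons. Fold changes of the comparisons had a Spearman's rho of 0.564 across all 14079 genes, which are not independent replicates. With the libraries summed per culture, 945 genes were higher and 866 lower in the knockout (edgeR, Benjamini-Hochberg; 4426 at an unadjusted p under 0.05). The count was 1357 and 179 without knockout replicate 1 or 2, 1205 and 225 without wild type replicate 1 or 2, 2818 by DESeq2 and 0 by limma-trend on TPM, where the median of all genes was 0.132. Of the 1811 genes called on summed cultures, 1454 were called in the same direction with length trends removed. Large rises on summed cultures were Txlnb (4.94 ± 0.38), Ptbp2 (4.08), Fsd1l (3.52), Anxa8 (2.88), Clcn6 (2.88), Vamp1 (2.81), the decoy receptor Tnfrsf11b (2.66) and Esr1 (2.65). Large falls were those of Ptbp1 (−6.94), Flna (−3.96), Fbln2 (−3.77), Il3ra (−3.65), Ripk1 (−3.48), Raph1 (−3.38) and Abhd14b (−3.28). In the NF-kB list 8 of 42 fell, with Ccl2 (−2.87) and Ccl7 (−2.81), and 3 rose; adjusted over the list alone, 12 and 6 (camera Benjamini-Hochberg adjusted p = 0.027; adjusted p = 0.911 with an estimated correlation).

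Exon use separated the genotypes at many genes. In Phldb2, a regulator of microtubule anchoring, a coding exon of 183 nt (chromosome 16, 45774163 to 45774345, minus strand, mm10) was included in 1.6% ± 0.1 (SD, n = 2) of transcripts in untreated wild type and 100% ± 0 in the knockout. In Ktn1, an anchor of kinesin, a coding exon of 84 nt (chromosome 14, 47726471 to 47726554, plus strand) went from 94.8% ± 3.2 to 19.5% ± 3.5. Pyruvate kinase, Pkm, carries a pair of mutually exclusive coding exons of 167 nt that PTB proteins are known to control. Inclusion of the upstream exon, used in the M1 enzyme (chromosome 9, 59675029 to 59675195, plus strand), went from 7.3% ± 0.3 to 51.6% ± 1.3. That of the downstream exon, used in the M2 enzyme (59675568 to 59675734), went from 92.8% ± 0.4 to 56.5% ± 0.5. Ptbp3, the paralog whose total level did not pass, gained a coding exon of 34 nt (chromosome 4, 59546149 to 59546182, minus strand), from 18.3% ± 1.0 to 87.2% ± 1.7. Picalm, a clathrin adaptor, gained a coding exon of 150 nt (chromosome 7, 90182219 to 90182368, plus strand), from 48.2% ± 1.5 to 92.3% ± 0.6. In edgeR's test of inclusion against exclusion reads over the exons of intermediate inclusion, the Benjamini-Hochberg adjusted p-values of these 6 exons ran from 6.26e-05 (both Pkm exons) to 0.00811 (Ptbp3).

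**Figure D3:**
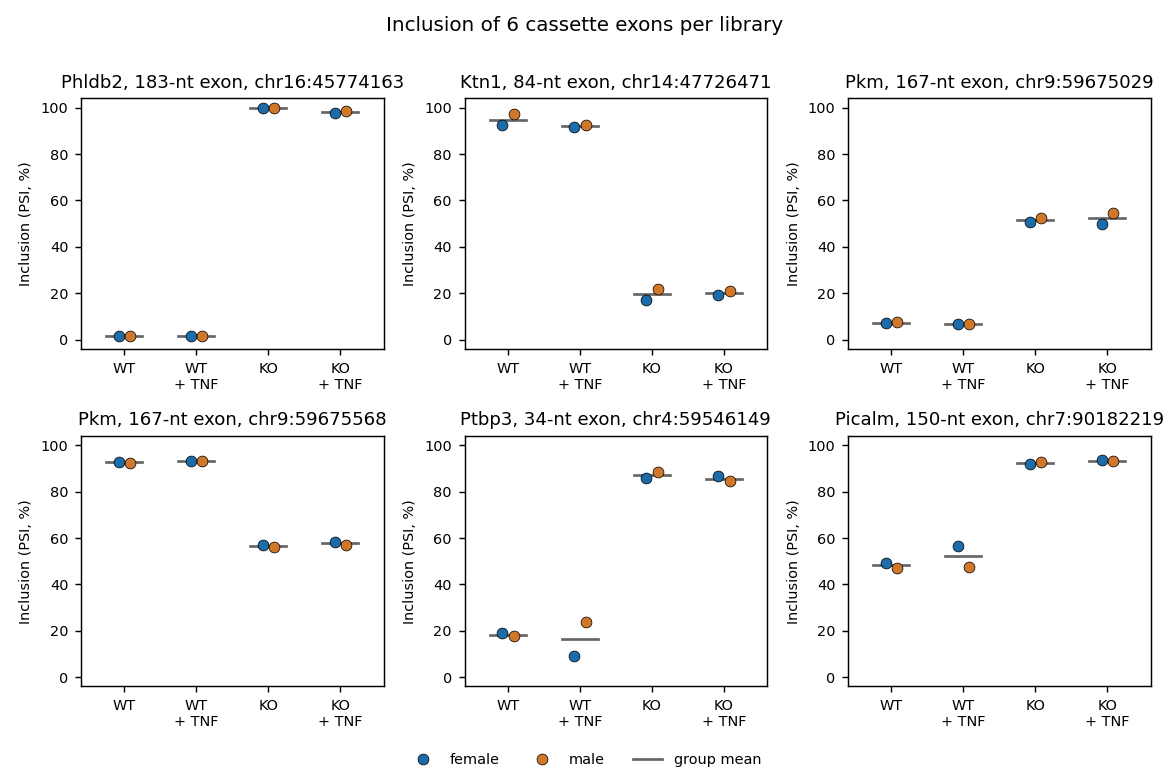
Inclusion (percent spliced in) of 6 exons, in Phldb2, Ktn1, Pkm (both exclusive exons), Ptbp3 and Picalm, in each of the 8 libraries, by group; each point is a library, coloured by sex, and the bar is the group mean. Inclusion of the upstream Pkm exon is 7.3 and 6.7% in wild type without and with TNF and 51.6 and 52.4% in the knockout.

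In that test of 5220 exons in 3328 genes, chosen after seeing the data, 292 exons rose and 110 fell in the untreated knockout (318 genes) and 317 rose and 106 fell with TNF (337 genes). Of these, 329 were called in both with the same direction and 3 with opposite directions, where independent lists would share 32.6, with the same reservation. The planned test over 32840 exons called 0 in every comparison (edgeR, Benjamini-Hochberg; 1029 exons at an unadjusted p under 0.05 untreated and 1070 with TNF), and limma on the logit of PSI called 1 untreated and 0 with TNF. Among 22 tested exons of 11 genes with PTB-regulated exons, 7 rose and 4 fell untreated (in 5 genes) and 5 rose and 3 fell with TNF (in 3 genes). They include both Pkm exons, the Ptbp3 exon, tropomyosin exons of Tpm1 (0.4 to 24.1% for the exon at 67029664 to 67029742 on chromosome 9, and 31.2 to 0.3% for that at 67032466 to 67032541). Others, called untreated, are exons of Tpm2 (99.6 to 36.7% and 0.6 to 66.4%) and an exon of 21 nt in Mef2d (2.2 to 19.4%). With TNF these Tpm2 and Mef2d exons did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0593, 0.0528 and 0.102). Among 51 exons of 17 endothelial adhesion and matrix genes, 4 rose and 2 fell untreated and 3 rose and 1 fell with TNF. Among them were a second Picalm exon (3.2 to 33.0%) and, called untreated but not with TNF, an Mbnl1 exon (61.7 to 78.9%). The Fn1 exon called lower untreated was 78.6% ± 30.3 in the knockout and 100% in the knockout with TNF, so its call rests on 1 library. Other large changes without TNF were rises in Pdlim5 (0 to 94.0%), Dennd1a (4.7 to 98.6%), Tnrc6a (3.5 to 96.8%), Kansl3 (4.0 to 97.1%) and Smap1 (3.0 to 95.2%). Inclusion fell in Mycbp2 (95.3 to 17.0%), Flnc (100 to 28.9%), Tmem87b (77.1 to 17.8%) and Map4 (87.5 to 30.8%). The largest changes with TNF also included Ralgapa2 (0 to 88.8%), Arhgef11 (84.9 to 17.6%) and the lipoprotein receptor Scarb1 (95 to 35.9%). These exons were called untreated as well, with changes of 88.8, −56.4 and −52.8 percentage points, in that order. Between replicates the median exon differed by 3.8 to 4.5 percentage points.

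For TNF averaged over genotypes, edgeR called 0 of the 5220 exons (Benjamini-Hochberg; smallest adjusted p 0.0518; 286 exons at an unadjusted p under 0.05), 0 in wild type (271 at an unadjusted p under 0.05) and 1 in the knockout. limma on the same exons called 0, 0 and 1. The exon called by edgeR in the knockout, of 38 nt in Bud23 (chromosome 5, 135063884 to 135063921, minus strand), was named after its values were seen. Its inclusion was 100% ± 0 untreated and 68.8% ± 42.6 with TNF, so the call rests on 1 library. Without knockout with TNF replicate 1 or 2, or untreated knockout replicate 1, 0 exons were called, and 3 without untreated knockout replicate 2. Leaving out a library lowered the genotype counts: untreated, 402 exons became 190 and 186 without knockout replicate 1 or 2 and 245 and 233 without wild type replicate 1 or 2. With TNF, 423 became 175 and 181 without knockout replicate 1 or 2 and 228 and 242 without wild type replicate 1 or 2. On libraries summed per culture 272 exons rose and 88 fell, where 191 and 182 were called without knockout replicate 1 or 2 and 388 and 420 without wild type replicate 1 or 2. The summed fits without a replicate left out a whole culture and also the sex term, so their counts come from a different model. limma on the summed libraries called 49 higher and 5 lower.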

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

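The tests of library depth, of fibroblast and smooth muscle markers and of other splits of the libraries were chosen only after the results were seen, as were the removal of length trends and the count of other splicing events. The response to TNF differed between genotypes for Fbln5, which fell with TNF by less in the knockout (interaction 2.38 on the log2 scale; 2.21 in the female and 2.56 in the male pair). For the interaction, camera at the preset correlation called 8 gene lists, and 0 with an estimated correlation, as did fry. The camera Benjamini-Hochberg adjusted p was 1.96e-09 for NF-kB and TNF target genes (adjusted p = 0.133 with an estimated correlation) and 2.94e-05 for flow-induced genes (16 of 18 positive, adjusted p = 0.217 with an estimated correlation). It reached 1.29e-10 for matrix genes (26 of 29 positive, 12 higher adjusted over the list alone, adjusted p = 0.664 with an estimated correlation). It was 0.00245 for arterial and Notch genes (16 of 20 positive), 0.0163 for endothelial identity genes (19 of 29 positive) and 0.0107 for fibroblast markers, whose median (0.60) and mean (−0.09) differ in sign; with an estimated correlation, adjusted p = 0.771, 0.777 and 0.521. For ribosomal protein genes it was 6.83e-29, with 78 of 78 negative, and for oxidative phosphorylation 4.55e-14, with adjusted p = 0.734 and 0.771 with an estimated correlation. Their median interactions were −0.68 and −0.40, and −0.24 and −0.02 (77 and 41 negative) with length trends removed.

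Ribosomal protein genes were lower in the knockout with TNF, with a median log2 fold change of −0.96. Library depth is argued against, because the totals of the knockout and wild-type libraries with TNF overlapped (a gap of −2.9 M counts). A length bias between libraries may account for part or all of it: 367 other genes of like level and short length had a median of −0.49, barely past the −0.48 that the test required. Those genes were longer, with a median of 1044 nt against 706 nt, so they may understate the bias. With each library's length trend removed 36 of the 78 genes were still lower (median −0.32), which may be a remainder. But a trend fitted over all genes may correct the shortest ones too little. That remainder, and whether the length trends come from the genotype or from the preparation of the libraries, stays open, and without knockout with TNF replicate 2 the uncorrected count was 0.

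Matrix genes fell with TNF in wild-type cells, and fewer contaminating cells of another type could lower them too. The abundant smooth muscle markers were divided. Their median log2 fold change was 0.15 (SD 1.08 over 5 markers, Acta2 2317 and 2590 CPM), where −1.62, or 50% of the fall of Fbln5, was required. As a set they argue against fewer smooth muscle cells. Pdgfrb, however, fell past that mark (−2.12, from 60.4 to 14.5 CPM), so a loss of cells that carry it is not excluded. Fewer fibroblasts cannot be told apart from a change within endothelial cells, because the 10 abundant fibroblast markers had a median of −0.85 with an SD of 0.90 (Col3a1 393.7 and 126 CPM, Gsn 782.7 and 661 CPM). Pooled over both types, the median of −0.59 (SD 0.98) fell short of −1.62 by more than that SD, which argues against a loss of both types together but, since fewer fibroblasts alone would do, not against that. The sort for Icam2 and Cd31 would remove such cells, and endothelial cells themselves can express several of these markers.

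Splits of the 8 libraries into 4 and 4 were counted for the averaged TNF comparison, and 2 of 35 gave at least its 272 calls. The other one was the split by genotype, with 2649, which is a structure of the libraries. With that split among the 35, the share could not be under 0.05 here. The count can therefore neither exclude chance nor argue for it. The split by sex gave 5, and no remaining split gave more than 1. Without a genotype-by-TNF term the real split gave 1 call, and 3 of 35 gave as many, with 2649 again the highest. The averaged comparison with the term was the planned one, but counting its splits was decided after the count without the term had been seen. For exons, the split by genotype set 492 apart and the highest other split 11. Only 1 of 35 was as large, the smallest share this count can give. If the 8 libraries are independent, that argues against chance. It cannot exclude chance, since the count was chosen after the results were seen. Were libraries that share a number 1 culture, only 3 splits would be left (492 by genotype, 6 by sex and 3 for the crossed one), too few for a share under 0.05.

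Splice events other than cassette exons were called between genotypes by edgeR with Benjamini-Hochberg adjustment. Of 2016 alternative acceptor events 34 were called in the untreated knockout (25 higher, 9 lower) and 53 with TNF (40 higher, 13 lower). Of 1662 alternative donor events 13 and 11 were called, and of 1210 retained introns 4 and 7, all of these introns lower in the knockout. On libraries summed per culture 86 acceptor and 27 donor events were called, and 4 retained introns, of which 1 was higher and 3 lower. TNF averaged over genotypes gave 2, 3 and 1 calls in these kinds of event, all higher.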

How the results depend on the processing

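The fits on 4 libraries, without a genotype-by-TNF term and with length trends removed, and the tests of exons of intermediate inclusion, were chosen after seeing the data. DESeq2 called 1732 genes for TNF in wild type, 46 for TNF in the knockout, and 1269 for TNF averaged. It called 1397 for the knockout untreated, 171 for the interaction and 2818 for summed cultures. limma-voom with culture as a random effect called 720, 493 and 2 for TNF in wild type, TNF averaged and the interaction. A 2-fold minimum left 243 genes for TNF in wild type, 93 averaged, 162 for the knockout untreated, 952 with TNF and 532 summed. limma-trend on TPM called 187 for the knockout untreated, 0 for the interaction and 0 for summed cultures. Without a genotype-by-TNF term 1 gene was called for TNF averaged. Fits on only the 4 libraries compared called 665 genes for TNF in wild type, 20 for TNF in the knockout, 2173 for the knockout untreated and 219 with TNF. With length trends removed the counts were 981 for TNF in wild type, 713 averaged and 900 for the knockout untreated. Except where fewer genes or libraries enter, the cause was not tested.

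As a replicate block, the culture number gave 1321 calls for TNF in wild type and 803 averaged, and left 0 for TNF in the knockout and 1 for the interaction. The deviations of same-numbered libraries correlated at 0.063 in wild type and 0.139 in the knockout, so the pairing is not established.

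Leaving out each library in turn gave 2 to 2274 genes for TNF in wild type, 0 to 0 for TNF in the knockout, and 3 to 1306 averaged. It gave 32 to 38 for the knockout untreated, 425 to 4970 with TNF, 0 to 591 for the interaction and 179 to 1357 for summed cultures. The planned exon test stayed at 0 to 0, and exons of intermediate inclusion gave 186 to 245 untreated, 175 to 242 with TNF, 182 to 420 summed and 0 to 1 for TNF averaged. A lone library in an arm is assumed to vary like the other groups. For exons, the summed fits left out a whole culture and also the sex term.

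Gene lists called with camera numbered 11 for TNF in wild type (0 with an estimated correlation, 4 with fry), 8 for TNF in the knockout (0, 0), and 12 averaged (1, 3). They numbered 8 for the knockout untreated (0, 0), 7 with TNF (0, 4), 8 for the interaction (0, 0) and 12 summed (0, 0). limma on PSI called 1 exon untreated. Restricting exons to intermediate inclusion gave 402 untreated, 423 with TNF and 360 summed, and summed cultures gave 557 at 0.1 to 0.9 and 54 with limma. On log2(TPM + 1) the median response of the NF-kB list was 0.678 and 0.802 in wild type and 0.403 in the female knockout. That of higher genes was 0.881 and 0.910 in wild type and 0.497 and 0.553 in the knockout (female, then male), and that of lower genes −0.303 in the male knockout. Pgm1, −3.57 in the untreated knockout, was 0.148 on TPM; the cause was not tested. Of 1416 alternative values of the 97 named results that passed, 1232 passed in the same direction, 183 no longer passed (134 with a library left out) and 1 reversed. Of 1360 for the 88 that did not pass, 91 passed and 59 differed in sign. Counts are high, so the spread between libraries, not depth, limits these results.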

Other observations

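The tests of reading frame and of sex were chosen only after the results were seen. Other gene lists add to the comparison of knockout and wild type with TNF (edgeR, Benjamini-Hochberg). Of 21 genes of endothelial-mesenchymal transition 8 rose, among them the integrin Itgb1 (1.11), the cadherin Cdh2 (1.18) and the receptor Tgfbr1 (0.88), and 2 fell, with Tgfb1 (−0.75); adjusted over the list alone, 10 and 2 (camera Benjamini-Hochberg adjusted p = 0.0618). Of 19 p53 targets 7 rose, with Mdm2 (1.26), Gdf15 (1.14) and the death receptor Fas (1.01), and 0 fell; adjusted over the list alone, 8 and 1 (0.139). Of 20 antigen presentation genes 6 rose, with H2-Q6 (1.15) and the peptide transporter Tap1 (0.93), and 6 did adjusted over the list alone (0.138). Of 34 interferon-stimulated genes 4 rose, with Ifit2 (1.04) and Samd9l (0.89), against 3 adjusted over the list alone (0.879). Of 25 parts of the TNF receptor pathway 5 rose, with the second TNF receptor Tnfrsf1b (1.16) and Tab3 (0.95), and 4 fell, with Ripk1 and Fam105b (−0.82); adjusted over the list alone, 7 and 4 (0.879). Of 21 cholesterol synthesis genes 6 fell, with Lss (−1.52) and Mvd (−0.73), and 1 rose; adjusted over the list alone, 6 and 1 (0.139).

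Most of the further lists went both ways with TNF, counted as rises and falls in the knockout. They were 6 and 3 of 29 endothelial identity genes (Ptprb 2.09, Clec14a 2.71, Rasip1 −1.26), 6 and 2 of 20 arterial genes (Fbln5, Bmx 1.13). They were 5 and 3 of 20 tip cell genes (Nrp1 1.02, Apln −1.12) and 5 and 4 of 20 hypoxia targets (P4ha1 1.06, Adm −1.11). They were also 6 and 4 of 20 stress response genes (Hspa5 0.94, Cebpb −1.23), 4 and 5 of 33 cell cycle genes (Mki67 1.17, Tyms −0.96), 2 and 3 of 19 immediate early genes (Egr1 1.99, Ier3 −1.35) and 4 and 2 of 16 complement and coagulation genes (Cd55 0.92, Plat −1.30). Of 44 splicing factors 6 rose and 7 fell (Mbnl1 0.93, Hnrnpl −0.77), and of 14 neuronal genes that PTB holds down 2 rose and 1 fell (Src −1.01). Of 6 lymphatic markers Flt4 rose (0.72) and Nts fell (−4.45), of 6 mesothelial and adipocyte markers Krt18 fell (−1.46), and 0 of 8 leukocyte markers passed. Adjusted over the list alone, the rises and falls were 7 and 4 for endothelial identity, 6 and 3 for arterial, 5 and 5 for tip cell and 6 and 5 for hypoxia genes. They came to 6 and 4 for stress response, 5 and 6 for cell cycle, 3 and 3 for immediate early and 4 and 2 for complement genes. They were 6 and 7 for splicing factors, 2 and 2 for neuronal, 2 and 1 for lymphatic, 0 and 1 for mesothelial and 0 and 0 for leukocyte genes. None of these lists was called by camera after Benjamini-Hochberg adjustment (smallest 0.249).

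With TNF in wild type, 1 of 33 cell cycle genes rose (camera Benjamini-Hochberg adjusted p = 0.0123; adjusted p = 0.666 with an estimated correlation) as did 1 of 14 neuronal genes (0.0366; adjusted p = 0.5 with an estimated correlation). By contrast, 18 of 21 cholesterol synthesis genes had negative fold changes with 0 past the test (0.0168; adjusted p = 0.5 with an estimated correlation). Sex was tested as a modifier, though with 1 female and 1 male library per group it cannot be told apart from differences between mice or cultures. For a TNF effect that differs between sexes, edgeR with Benjamini-Hochberg adjustment called 0 genes (128 at an unadjusted p under 0.05). It called 0 for a genotype effect that does (1833, smallest adjusted p 0.0629). By chance 704 would be expected in each, so the 0 calls for genotype do not show that the pairs were alike. These were not run with another tool.

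A hypothesis prompted by a single gene seen in these data was that exons whose length is not a multiple of 3 lower the transcripts that gain them. In the untreated knockout, 8 of 46 genes with such a gained exon were lower (17.4%) against 8 of 150 genes whose gained exon kept the frame (5.3%; one-sided Fisher exact p = 0.0146, 0.0438 adjusted over 3 comparisons by Benjamini-Hochberg). It was p = 0.05 with summed cultures (10 against 16) and p = 0.318 with TNF (9 against 23), and without the gene that prompted it the Fisher exact p-values were 0.0321, 0.0861 and 0.425, with adjusted values of 0.0963, 0.129 and 0.425. Other members were Fmnl3 (−3.11), Cxcl16 (−1.90), Ripk2 (−1.28) and Haus4 (−1.20). The data leave this open, since the difference may rest on the choice of comparison, and the exons of Fmnl3, Haus4 and Cxcl16 are annotated without coding sequence.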
